A study of Mus musculus with 9 samples.

How the data were processed

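Bulk RNA was sequenced from 9 libraries of mouse splenic CD4 T cells, 3 libraries for each of 3 subsets. Per the labels' protocols, C57BL/6 reporter mice were infected with clone 13 of lymphocytic choriomeningitis virus (LCMV Cl13), a strain that persists, and cells were sorted on day 14. The mice report Il21 through a red fluorescent protein (tRFP), and the 10BiT transgene reports Il10. Sorted cells were tRFP-positive and CD44-positive, and the sample titles add PD-1hi. CXCR5-positive cells are called Tfh (T follicular helper), CXCR6-positive cells Th1 (T helper 1), and cells negative for both receptors memory-like. Each subset was sorted as 5000 cells from 3 independent donor mice, and whether the subsets share mice is not given in the sources used here. Libraries were made with Smart-seq2, a full-length cDNA method with PCR amplification, and sequenced on a NextSeq. One label speaks of single cells, but the table holds a library per subset and replicate. Smart-seq2 does not mark strand, so fragments of overlapping or antisense genes cannot be told apart.

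The authors deposited a table of expected counts, that is estimated fragments per gene and library, with FPKM values beside them, per the file headers. Its column names are those of Cuffdiff read group tracking. TopHat and the genome build mm10 are named in the submitters' processing notes. Versions and the gene annotation are not given in the sources used here. Of the fragment counts above 0, 97.8% were whole within 0.001, and all were rounded to whole numbers. The deposited FPKM values carry a scaling factor per library set by the authors, per the file headers, and were used only for alternatives. The table numbers replicates from 0 to 2 and the labels from 1 to 3, so a replicate number here only names a library within its group. The authors marked Rn45s, a ribosomal RNA precursor, as too deep to quantify in all 9 libraries, and it is listed at 0. Gene names that are spreadsheet dates, 25 names behind which stand 27 genes, were left out of totals and tests. They held 0.205% to 0.230% of the fragments per library. Left in were 24316 genes. Reads assigned between near-identical genes could be split in ways the sources used here do not give, so values of Ccl3, Ly6c2, Lilr4b, Eif3j1, the granzyme and the Klr families are uncertain.

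Total fragments per library were 10345300, 10845150 and 9009053 in Tfh replicates 1 to 3 and 11179279, 9710901 and 11330408 in Th1. In memory-like replicates they were 10317005, 9516249 and 3461936. The shallowest library, memory-like replicate 3, had 10094 genes with at least 10 fragments, against 11089 to 11412 in the other 8. A gene at 0 fragments could stand at up to 3 fragments. A fold against a group with 0 fragments is therefore a lower bound. It was computed against a floor of 3 fragments over the pooled libraries of that group. With 1 to 3 fragments the ratio is given with an exact 95% counting interval. Such intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

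Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr, which left 11669, and libraries were scaled by TMM. All 9 libraries entered a quasi-likelihood fit without intercept and without covariates, so that the spread was shared, with a biological coefficient of variation of 0.209. In what follows, edgeR adjusted p is the p-value of the quasi-likelihood test of that fit after Benjamini-Hochberg adjustment over the genes tested, called at 0.05. Levels are TMM-scaled CPM (counts scaled to a common library size), as mean ± SD over the 3 libraries of a group. Log2 fold changes come from the fit. Their SE was worked back from the test, as the absolute log2 fold change over the square root of the F statistic. It is not an SE given by the model, and for genes near 0 fragments it may be too small. The subsets were compared in pairs, and all 3 at once with an F test. A gene was called highest in a subset by the larger of its p-values against the other subsets, with both fold changes above 0 (an intersection-union test). The memory-like position is the mean, over genes called between Th1 and Tfh, of the library's log2 CPM on a line from the Tfh mean at 0 to the Th1 mean at 1. Coordinates are those of GENCODE vM21 on GRCm38, the assembly of mm10, found by gene symbol, and cover the whole gene with its exons, introns and untranslated regions.

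Gene lists numbered 28. They cover the Tfh program, the Th1 program, cytotoxic effector molecules, memory and central memory genes, and coinhibitory receptors and exhaustion genes. They also cover Treg and Tr1 genes, T cell cytokines, chemokines and trafficking receptors, T cell fate transcription factors, immediate early genes induced by the T cell receptor, and proliferation. Lists of metabolism and stress hold interferon-stimulated genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, cytosolic ribosomal proteins, and heat shock and dissociation stress. Further lists hold CD4 T cell identity genes, mitochondrially encoded transcripts, and sex-linked transcripts. The last hold markers of B cells, plasma cells, CD8 T and NK cells, innate-like and gamma delta T cells, monocytes and macrophages, neutrophils, dendritic cells, and erythroid cells and platelets. Some genes stand in several lists, so the tests of these lists are not independent. Examples are Id3 and Slamf6 in the Tfh program and the memory list, and Prdm1 and Il2ra in the Th1 program and the Treg and Tr1 list. Fgl2 is in the cytotoxic list and the Treg and Tr1 list. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 78 tests of 26 lists. The mitochondrial list had 0 tested members and the neutrophil list 2, so these lists were not tested. With a correlation estimated from the data, 12 of the 37 calls held. These were the Tfh and Th1 programs in all 3 comparisons, cytotoxic molecules and the Treg and Tr1 list in Th1 against Tfh and in memory-like against Th1, the memory list in memory-like against Th1, and glycolysis in memory-like against Tfh. A p-value of the preset test alone is weak evidence here, since splits of the libraries that mix the subsets also gave many calls.

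Genes are named by a rule. It takes the 10 largest changes in each direction of a comparison past the threshold, without overlap between libraries and with at least 10 CPM in the higher group. Unnamed, predicted and receptor segment genes are not taken. It adds the genes of the sort and the reporters, up to 4 members of each list with the lowest adjusted p, the 10 genes highest in each subset, and the most abundant markers of other cells. The text gives the part of them that shows each group, and says so where a gene falls outside the rule. The samples' groups, the tests of genes and lists, the lists, this rule and the alternatives, but for 3 named below, were fixed before the data were examined. Tests of explanations chosen later are named where they are given. Alternatives were other scalings, filters, tools (DESeq2 1.42.0, limma 3.58.1), a fold threshold of 1.5, FPKM in place of counts, a replicate block, fits of 6 libraries and leaving out each library. For lists they were also the estimated correlation, lists without the genes of the sort, and the test fry. Fry asks whether a list changes at all, where camera sets it against the other genes. Added after seeing the data were thinning of all libraries to the shallowest, a Lars2 covariate and leaving out Lars2. Tables were read with Python 3.11.15 and pandas 2.3.3.

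The tests were tried on simulated counts with 200 changed genes and the real libraries' depths. Of genes set 2-fold apart, 60% were recovered for Th1 against Tfh (11456 genes run), 59.1% for memory-like against Tfh (11455 genes) and 52.3% for memory-like against Th1 (11471 genes). At 4-fold these shares were 80%, 84.6% and 87.7%, and at 1.5-fold 42.4%, 22.4% and 21.2%. False calls made up 2.46%, 2.68% and 8.7% of the calls in that order. A position set to 0.3 came out at 0.311. That was a separate run with far more changed genes than 200, all set 4-fold apart between Th1 and Tfh, so its signal was stronger.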

Results

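Gene expression was measured in 9 libraries of activated splenic CD4 T cells that express the Il21 reporter, taken from mice on day 14 of infection with a persisting strain of lymphocytic choriomeningitis virus. The cells fell into 3 subsets of 3 libraries each: CXCR5-positive follicular helper cells (Tfh), CXCR6-positive T helper 1 cells (Th1) and cells with neither receptor (memory-like). Depth was 9009053 to 10845150 fragments in Tfh and 9710901 to 11330408 in Th1. Memory-like libraries had 10317005, 9516249 and 3461936 fragments, so the last of them has the largest counting error. The design asks how the 3 subsets of Il21-expressing cells differ from each other. Values below are TMM-scaled CPM, as mean ± SD with n = 3, and edgeR adjusted p stands for the quasi-likelihood test with Benjamini-Hochberg adjustment.

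Genes that define the sort differed between subsets as sorted. Cxcr5, the receptor that guides cells into follicles (chromosome 9, 44511787 to 44561877), stood at 927 ± 99.01 CPM in Tfh, 142 ± 10.9 in memory-like and 26.2 ± 3.71 in Th1 cells (n = 3 each). Cxcr6, a receptor for Cxcl16 (chromosome 9, 123806475 to 123811760), stood at 740.2 ± 109 CPM in Th1 against 15.2 ± 6.40 in Tfh and 14 ± 1.20 in memory-like cells. Il21 was detected in every subset, at 108 ± 6.48 CPM in Tfh, 89.4 ± 13.8 in memory-like and 60.9 ± 2.25 in Th1 cells. It was lower in Th1 than in Tfh (log2 fold change -0.83, SE 0.13, edgeR adjusted p = 0.000143). Memory-like and Tfh cells did not differ in it past the threshold (log2 fold change -0.28, SE 0.13, edgeR adjusted p = 0.244). Against Th1, Il21 was higher in memory-like cells by a log2 fold change of 0.55 (SE 0.13, edgeR adjusted p = 0.0113). That call was lost without memory-like replicate 1 (edgeR adjusted p = 0.0837, 0.00107 to 1.0 over the alternatives). Pdcd1, which encodes PD-1, was highest in Tfh at 1420 ± 184 CPM, against 731 ± 70.9 in Th1 and 657 ± 32.6 in memory-like cells. Memory-like and Th1 cells did not differ in it past the threshold (log2 fold change -0.15, SE 0.10, edgeR adjusted p = 0.354). Il10, an inhibitory cytokine, reached 483 ± 61.9 CPM in Th1 against 195 ± 30.4 in Tfh and 193 ± 52.3 in memory-like cells. Both differences passed (edgeR adjusted p = 7.22e-06 and 2.94e-05). Cd44 did not differ past the threshold in any pair, with 417 ± 18.7, 439 ± 42.2 and 369 ± 33.8 CPM in Tfh, Th1 and memory-like cells. With the replicate number as a block, its lower level in memory-like than in Th1 cells did pass. Cd4 was slightly higher in Th1 than in Tfh, at 1081 ± 15 against 858 ± 51.9 CPM (log2 fold change 0.33, SE 0.07, edgeR adjusted p = 0.00248). Neither pair with memory-like cells (960.4 ± 29.7 CPM) passed. A test against a fold of 1.5 called neither the Cd4 difference nor those of Il21.

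**Figure D1:**
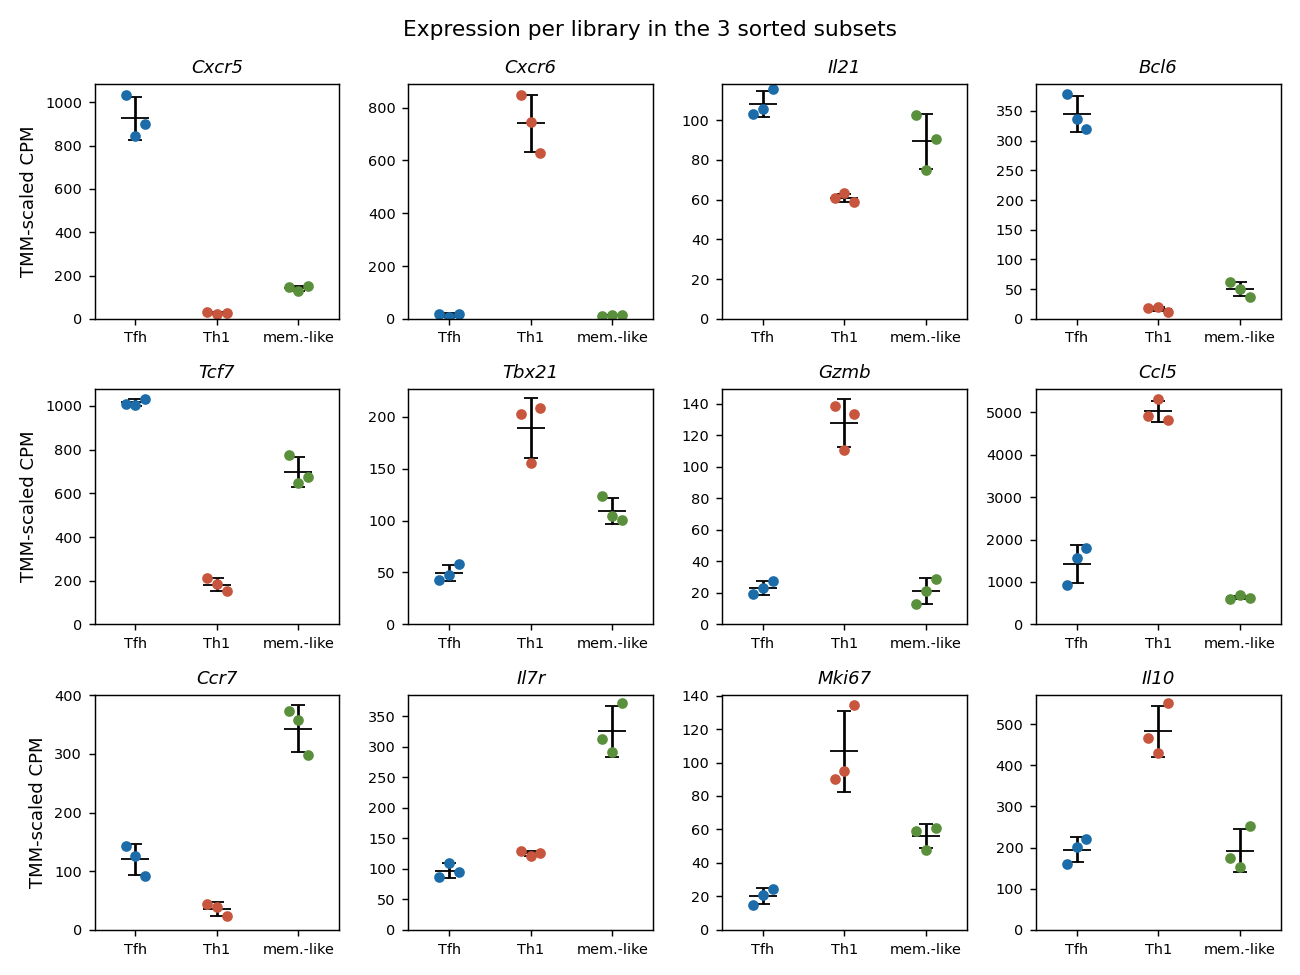
Levels of 12 genes in TMM-scaled CPM (y axis) for the 3 libraries of each subset (x axis); points are libraries, with the group mean and an SD bar. Cxcr5 is highest in Tfh, Cxcr6 and Gzmb in Th1, and Ccr7 and Il7r in memory-like cells.

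The 3 subsets lay apart in a scaling of the libraries by their leading log2 fold changes. Memory-like libraries stood between the others on the first axis, which held 40.03% of the variance, and above them on the second, which held 14.5%. The mean distance was 3.78 between Tfh and Th1 libraries, 3.12 between memory-like and Tfh and 3.00 between memory-like and Th1. Within a subset it was 2.42 to 2.49. An F test called 2674 of 11669 genes as differing among the subsets.

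**Figure D2:**
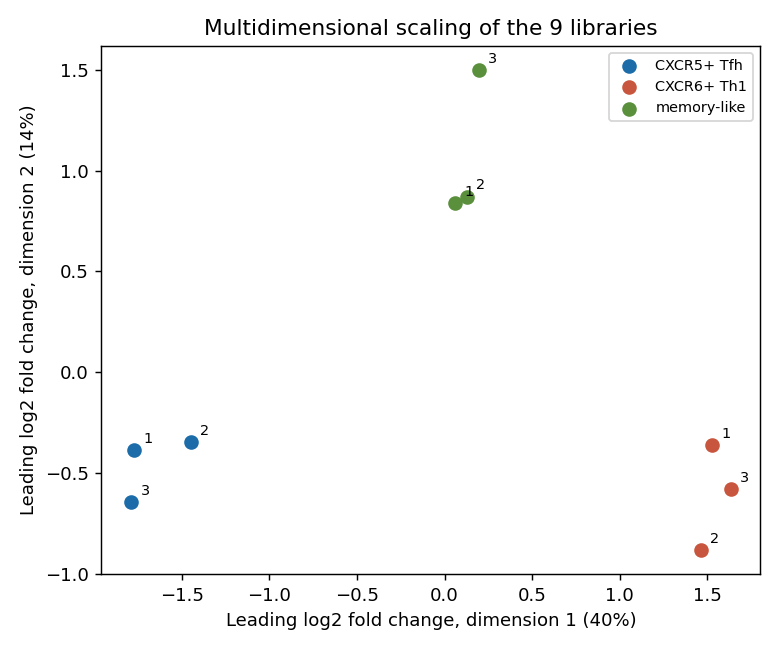
Multidimensional scaling of the 9 libraries by leading log2 fold change, dimension 1 (x axis) against dimension 2 (y axis); each point is a library, coloured by subset and numbered by replicate. Memory-like libraries lie at 0.062 to 0.197 on dimension 1, between Tfh (-1.79 to -1.45) and Th1 (1.46 to 1.63).

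The first comparison was of Th1 with Tfh cells, the pair that lay farthest apart. Transcripts of the follicular program were far lower in Th1. Bcl6, the transcription factor that directs the Tfh fate (chromosome 16, 23965052 to 23988852), stood at 16.6 ± 4.03 CPM in Th1 against 344 ± 30.2 in Tfh (log2 fold change -4.38, SE 0.19, edgeR adjusted p = 3.11e-11). Ascl2, a factor that induces Cxcr5, stood at 2.80 ± 0.641 against 184 ± 16.3 CPM (log2 fold change -6.04, SE 0.19, edgeR adjusted p = 9.24e-13). Sostdc1, a secreted antagonist of bone morphogenetic proteins, stood at 61.8 ± 2.69 against 2162 ± 344 CPM (log2 fold change -5.13, SE 0.11, edgeR adjusted p = 4.53e-15). Nkg7, a granule protein of cytotoxic cells, was higher in Th1 at 2312 ± 105 against 352 ± 102 CPM (log2 fold change 2.71, SE 0.16, edgeR adjusted p = 1.27e-09). So was Selplg, the selectin ligand PSGL-1, at 1146 ± 142 against 267 ± 23.6 CPM (log2 fold change 2.10, SE 0.10, edgeR adjusted p = 1.64e-10). In all, 1498 genes were higher and 1303 lower in Th1 than in Tfh cells, of which 733 and 541 differed by at least 2-fold. Libraries of the pair did not overlap for 38.3% of genes, where chance gives 10%.

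Of the Tfh program, 22 of 27 tested members were lower in Th1, 1 was higher and 4 did not pass (camera adjusted p = 1.44e-70, and adjusted p = 0.00193 with an estimated correlation). The counts were 2 higher and 22 lower adjusted over the list alone. Id3, a repressor of E proteins, was among the lower, with a log2 fold change of -3.36 (SE 0.11, edgeR adjusted p = 1.75e-12). In the Th1 program 26 of 30 were higher, 2 lower and 2 not past (camera adjusted p = 6.16e-48, and adjusted p = 0.00193 with an estimated correlation). It was 26 higher and 2 lower adjusted over the list alone. Ifngr1, an interferon gamma receptor chain, rose from 26.97 ± 5.83 to 231 ± 31.6 CPM. Lgals1, galectin-1, rose from 824 ± 29.1 to 2169 ± 131 CPM. Both programs hold genes of the sort, and without these genes both were still called (camera adjusted p = 9.2e-59 and 6.7e-43). That check was run with the preset correlation only, which alone is weak evidence here. Of the cytotoxic effector molecules 14 of 23 were higher, 2 lower and 7 not past the threshold (camera adjusted p = 1.44e-09, and adjusted p = 0.0267 with an estimated correlation). In this list 14 were higher and 2 lower adjusted over the list alone. Fasl, the Fas ligand, stood at 50.2 ± 12.3 CPM in Th1 against 5.69 ± 0.802 in Tfh, and Fgl2 at 41.8 ± 10.5 against 1.49 ± 0.979. Of the Treg and Tr1 genes 14 of 22 were higher, 1 lower and 7 not past the threshold (camera adjusted p = 1.40e-05, and adjusted p = 0.0183 with an estimated correlation). The counts were 14 higher and 2 lower adjusted over the list alone. Prdm1, which encodes Blimp-1, had a log2 fold change of 1.61 (SE 0.14, edgeR adjusted p = 1.17e-07). For Tnfrsf18, a costimulatory receptor, it was 0.98 (SE 0.09, edgeR adjusted p = 2.40e-07).

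Proliferation genes were higher in Th1 for 37 of 40 members, lower for 0 and not past for 3 (camera adjusted p = 1.74e-29, but adjusted p = 0.0537 with an estimated correlation). It was 37 higher and 0 lower adjusted over the list alone. Mki67, a marker of cycling cells, stood at 107 ± 24.4 against 20.2 ± 4.65 CPM. Top2a, topoisomerase II alpha, stood at 178 ± 14.2 against 48.05 ± 3.54, and Ccnb2, a mitotic cyclin, at 87.04 ± 17.7 against 10.8 ± 2.93. Of the memory genes 9 of 30 were higher, 12 lower and 9 not past the threshold (camera adjusted p = 1.40e-05, but adjusted p = 0.0537 with an estimated correlation). In this list 10 were higher and 12 lower adjusted over the list alone. Tcf7, which encodes TCF-1 (chromosome 11, 52252371 to 52283014), stood at 182 ± 29.9 CPM in Th1 against 1016 ± 14.8 in Tfh (log2 fold change -2.48, SE 0.11, edgeR adjusted p = 4.63e-11). Il6st, a chain of the IL-6 receptor, stood at 23.7 ± 3.33 against 132 ± 18.8. Among chemokines and trafficking receptors 19 of 31 were higher, 6 lower and 6 not past the threshold (camera adjusted p = 1.10e-05, but adjusted p = 0.0814 with an estimated correlation). The counts were 19 higher and 6 lower adjusted over the list alone. Ccr2 stood at 26.7 ± 6.17 against 1.14 ± 0.577 CPM and S1pr4, a sphingosine phosphate receptor, at 299 ± 19.1 against 81.8 ± 6.19. Of the T cell cytokines 5 of 21 were higher, 12 lower and 4 not past the threshold (camera adjusted p = 0.00129, but adjusted p = 0.117 with an estimated correlation). It was 5 higher and 12 lower adjusted over the list alone. Il4, a cytokine of helper cells in follicles, stood at 2.45 ± 0.416 against 35.1 ± 8.13 CPM, and Lta, lymphotoxin alpha, at 15.2 ± 2.30 against 56.3 ± 8.71.

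Glycolysis genes were lower in Th1 for 10 of 20, higher for 1 and not past for 9 (camera adjusted p = 0.000136, but adjusted p = 0.0538 with an estimated correlation). In this list 1 was higher and 12 lower adjusted over the list alone. Tpi1, triosephosphate isomerase, stood at 175 ± 20.1 against 416 ± 74.1 CPM, and Aldoa, an aldolase, at 660.4 ± 26.5 against 1241 ± 115. Cytosolic ribosomal protein genes were lower for 25 of 54, higher for 0 and not past for 29 (camera adjusted p = 0.000166, but adjusted p = 0.578 with an estimated correlation). The counts were 0 higher and 30 lower adjusted over the list alone. Rps29 was the most clearly lower of them, at 1625 ± 32.9 against 2582 ± 212 CPM. Of the heat shock and dissociation stress genes 2 of 24 were higher, 11 lower and 11 not past the threshold (camera adjusted p = 0.00633, but adjusted p = 0.382 with an estimated correlation). It was 3 higher and 11 lower adjusted over the list alone. The call of the heat shock list was lost without Th1 replicate 2 (adjusted p = 0.0619, 0.00193 to 0.382 over the alternatives). Fos and Egr1 were lower in Th1 at 288 ± 39.7 and 279.7 ± 21.4 CPM, against 672 ± 50.4 and 616 ± 86.8 in Tfh. Ier2 was higher at 584 ± 74.5 against 349.7 ± 10.7. Among immediate early genes induced by the T cell receptor 9 of 29 were higher, 9 lower and 11 not past the threshold (camera adjusted p = 0.884). In this list 9 were higher and 10 lower adjusted over the list alone. Rgs1 was higher at 514 ± 25.5 against 189 ± 20.8 CPM. Of the cholesterol synthesis genes 4 of 23 were higher, 3 lower and 16 not past the threshold (camera adjusted p = 0.837). The counts were 4 higher and 3 lower adjusted over the list alone. Tm7sf2 was lower at 6.55 ± 2.31 against 34.96 ± 1.13 CPM. Median, mean and test differed in sign for the lists of immediate early genes, coinhibitory receptors, T cell fate factors and innate-like T cells.

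The largest decreases were of genes that were near or at 0 fragments in Th1. Gfra4, a coreceptor for a neurotrophic factor (chromosome 2, 131039632 to 131043088), was at least 463-fold lower, Grtp1 at least 221-fold, Pipox at least 157-fold and Tuba8 at least 123-fold. Pstpip2 was 440-fold lower (exact 95% counting interval 78.5 to 17400). Mef2b, a transcription factor, fell from 64.7 ± 8.31 to 0.317 ± 0.320 CPM (log2 fold change -7.62, SE 0.41, edgeR adjusted p = 4.14e-10). On the other side stood Igfbp7, a secreted binding protein, at 40.9 ± 7.93 against 0.121 ± 0.210 CPM (log2 fold change 8.15, SE 0.52, edgeR adjusted p = 3.12e-09). Adam8, a membrane protease, stood at 49.4 ± 8.78 against 0.395 ± 0.684 CPM (log2 fold change 6.83, SE 0.67, edgeR adjusted p = 6.19e-07), and Plac8 at 93.8 ± 8.09 against 2.89 ± 1.63 (log2 fold change 4.99, SE 0.30, edgeR adjusted p = 1.87e-09).

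Markers of other cells were scarce, and some moved with the subsets. C1qc, a complement gene of macrophages, stood at 9.21 ± 2.0 CPM in Th1, 12.3 ± 2.29 in memory-like and 1.60 ± 1.46 in Tfh cells. Csf1r, a macrophage growth factor receptor, stood at 2.995 ± 1.45, 6.08 ± 1.92 and 0.0911 ± 0.158 CPM in the same order. Of the monocyte and macrophage markers 7 of 18 were higher, 3 lower and 8 not past the threshold (camera adjusted p = 0.197, and adjusted p = 0.481 with an estimated correlation). It was 7 higher and 4 lower adjusted over the list alone. Without Tfh replicate 2 this list was called (adjusted p = 0.0230, 0.0230 to 0.481 over the alternatives). Tyrobp, an adaptor of NK and myeloid cells, stood at 10.7 ± 2.17 CPM in Th1 against 0.612 ± 0.260 in Tfh (edgeR adjusted p = 3.47e-06). The CD8 T and NK list was not called (2 of 4 higher, 0 lower, camera adjusted p = 0.111). In this list 2 were higher and 1 lower adjusted over the list alone. Cd8a had at most 5 fragments in any library. Of the plasma cell markers 2 of 4 were higher, 0 lower and 2 not past the threshold (camera adjusted p = 0.0842). The counts were 2 higher and 0 lower adjusted over the list alone. Of the dendritic cell markers 3 of 8 were higher, 0 lower and 5 not past the threshold (camera adjusted p = 0.107). It was 3 higher and 0 lower adjusted over the list alone. Of the innate-like T cell markers 1 of 6 was higher, 2 lower and 3 not past the threshold (camera adjusted p = 0.171). In this list 1 was higher and 2 lower adjusted over the list alone. Of B cell markers 2 of 10 were higher and 2 lower (camera adjusted p = 0.882). The counts were 2 higher and 2 lower adjusted over the list alone. Ms4a1 had 45 fragments, all in Tfh replicate 2. Jchain, a plasma cell gene too uneven to test, had 1244 of its 1305 fragments in Th1 replicate 2. That library also held 171 of the 415 fragments of Pf4 and 169 of the 271 of Ppbp, which are platelet genes. Of the erythroid and platelet markers 2 of 8 were higher, 0 lower and 6 not past the threshold (camera adjusted p = 0.150). It was 2 higher and 0 lower adjusted over the list alone. Without Th1 replicate 3 this list was called (adjusted p = 0.0384, 0.0384 to 0.667 over the alternatives). Of the neutrophil markers, S100a8 and S100a9 had 4 and 8 fragments over the 9 libraries. Sex-linked transcripts did not differ, with 0 of 4 higher and 0 lower (camera adjusted p = 0.837). In this list 0 were higher and 0 lower adjusted over the list alone. Ddx3y stood at 95.01 ± 2.19 and 98.2 ± 6.16 CPM in Th1 and Tfh cells.

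A test against a fold of 1.5 in place of 0 called 588 genes higher and 421 lower in Th1 than in Tfh cells. Thy1 was higher in Th1, at 1658 ± 213 against 589.7 ± 86.8 CPM (log2 fold change 1.49, SE 0.11, edgeR adjusted p = 2.16e-08). The 10BiT mice carry a Thy1.1 transgene that reports Il10, and a table by gene cannot tell its fragments from those of Thy1.

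**Figure D3:**
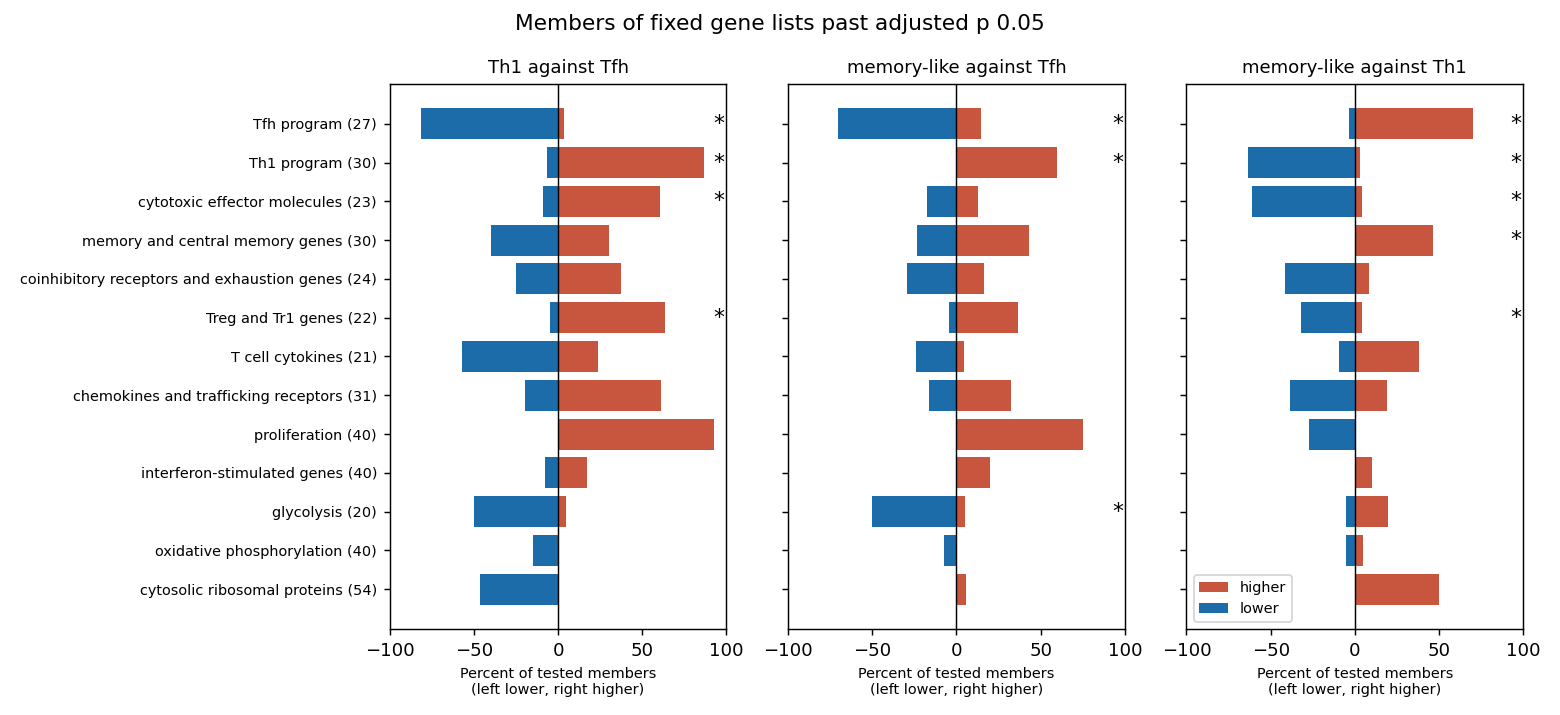
Percent of tested members of 13 gene lists (y axis) that were higher (red bars, to the right) or lower (blue bars, to the left) in each of the 3 comparisons (x axis of each panel, from 0); an asterisk marks an adjusted p under 0.05 with an estimated correlation. The Tfh and Th1 programs carry the asterisk in all 3 comparisons.

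Memory-like cells were next compared with Tfh cells, and 579 genes were higher and 498 lower in memory-like cells, of which 279 and 224 differed by at least 2-fold. Cells without CXCR5 held less of the follicular program. Bcl6 stood at 49.99 ± 12.2 CPM against 344 ± 30.2 in Tfh (log2 fold change -2.76, SE 0.17, edgeR adjusted p = 1.33e-08). Ascl2 stood at 17 ± 1.92 against 184 ± 16.3 (log2 fold change -3.44, SE 0.16, edgeR adjusted p = 6.32e-10). Il7r, the receptor for the survival cytokine IL-7 (chromosome 15, 9505788 to 9530176), was higher in memory-like cells at 325 ± 41.4 against 97.2 ± 12.1 CPM (log2 fold change 1.74, SE 0.12, edgeR adjusted p = 3.10e-08). So was Klf2, a factor that controls exit from lymphoid tissue, at 346 ± 26.98 against 121 ± 20.5 CPM (log2 fold change 1.51, SE 0.14, edgeR adjusted p = 6.52e-07). Il18r1, the IL-18 receptor, stood at 86.4 ± 16.2 against 16.1 ± 3.26 (log2 fold change 2.42, SE 0.17, edgeR adjusted p = 5.18e-08). Libraries of the pair did not overlap for 26.2% of genes, where chance gives 10%.

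Of the Tfh program 4 of 27 were higher, 19 lower and 4 not past the threshold (camera adjusted p = 1.22e-38, and adjusted p = 0.00440 with an estimated correlation). The counts were 5 higher and 20 lower adjusted over the list alone. Sostdc1 was lower but still abundant, at 759 ± 2.01 CPM against 2162 ± 344 (log2 fold change -1.51, SE 0.10, edgeR adjusted p = 1.33e-08). Of the Th1 program 18 of 30 were higher, 0 lower and 12 not past the threshold (camera adjusted p = 1.60e-28, and adjusted p = 0.00440 with an estimated correlation). It was 20 higher and 2 lower adjusted over the list alone. Bhlhe40, a transcription factor, rose to 1016 ± 171 from 391 ± 17.2 CPM, Itgb1, an integrin chain, to 1657 ± 205 from 708 ± 82.9, and S100a4 to 1082 ± 67.1 from 428 ± 96.98. Glycolysis genes were lower for 10 of 20, higher for 1 and not past for 9 (camera adjusted p = 2.77e-05, and adjusted p = 0.0430 with an estimated correlation). In this list 1 was higher and 10 lower adjusted over the list alone. Tpi1 stood at 235 ± 9.12 CPM, Aldoc at 6.75 ± 3.08 against 25.3 ± 2.43, and Pfkp, a phosphofructokinase, at 149 ± 28.3 against 245 ± 22.5.

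Of the proliferation genes 30 of 40 were higher, 0 lower and 10 not past the threshold (camera adjusted p = 3.80e-34, but adjusted p = 0.0534 with an estimated correlation). The counts were 35 higher and 0 lower adjusted over the list alone. Top2a stood at 130.1 ± 18.3 CPM against 48.05 ± 3.54 in Tfh, and Stmn1, stathmin, at 121 ± 22.3 against 45.1 ± 3.61. Of the memory genes 13 of 30 were higher, 7 lower and 10 not past the threshold (camera adjusted p = 0.000294, but adjusted p = 0.110 with an estimated correlation). It was 15 higher and 8 lower adjusted over the list alone. Il6st, at 45.96 ± 8.69 CPM, was among the lower ones. Of the chemokines and trafficking receptors 10 of 31 were higher, 5 lower and 16 not past the threshold (camera adjusted p = 0.00228, but adjusted p = 0.209 with an estimated correlation). In this list 11 were higher and 5 lower adjusted over the list alone. Itga4, an integrin chain, stood at 771 ± 89.8 against 289 ± 51.6 CPM. Of the Treg and Tr1 genes 8 of 22 were higher, 1 lower and 13 not past the threshold (camera adjusted p = 0.00263, but adjusted p = 0.0537 with an estimated correlation). The counts were 8 higher and 3 lower adjusted over the list alone. Ebi3, a cytokine chain, stood at 22.6 ± 3.995 against 6.55 ± 1.66 CPM.

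Of the interferon-stimulated genes 8 of 40 were higher, 0 lower and 32 not past the threshold (camera adjusted p = 0.000248, but adjusted p = 0.242 with an estimated correlation). It was 8 higher and 1 lower adjusted over the list alone. Slfn1 stood at 409.7 ± 31.2 against 273 ± 26.3 CPM and Ifi44 at 55.9 ± 6.29 against 32.4 ± 3.13. Among oxidative phosphorylation genes 0 of 40 were higher, 3 lower and 37 not past the threshold (camera adjusted p = 0.000461, but adjusted p = 0.243 with an estimated correlation). In this list 0 were higher and 6 lower adjusted over the list alone. Among CD4 T cell identity genes 1 of 15 was higher, 6 lower and 8 not past the threshold (camera adjusted p = 0.00606, but adjusted p = 0.209 with an estimated correlation). The counts were 1 higher and 6 lower adjusted over the list alone. Cd3d, a chain of the T cell receptor complex, stood at 1089 ± 103 against 1558 ± 59.7 CPM. Among cytotoxic molecules 3 of 23 were higher, 4 lower and 16 not past the threshold (camera adjusted p = 0.892). It was 4 higher and 5 lower adjusted over the list alone. Cd160 was lower at 6.77 ± 2.24 against 33.3 ± 12.6 CPM. Median, mean and test differed in sign for the cytotoxic list and those of immediate early genes, heat shock, B cell markers, innate-like T cells and sex-linked transcripts.

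The largest decreases in memory-like cells included Gal, a neuropeptide gene (chromosome 19, 3409915 to 3414544), at least 161-fold from 20.4 ± 7.31 CPM in Tfh to 0 fragments. Il13ra1, an IL-13 receptor chain, stood at 0.279 ± 0.483 against 54.4 ± 8.46 CPM. Padi4, an enzyme that converts arginine to citrulline, stood at 9.61 ± 0.723 against 159.5 ± 28.2 CPM (log2 fold change -4.07, SE 0.19, edgeR adjusted p = 5.48e-10). The largest increases included Ccl1, a chemokine, at 12.3 ± 12.3 against 0.182 ± 0.316 CPM (log2 fold change 5.93, SE 0.95, edgeR adjusted p = 0.000452). Vax2 stood at 27.02 ± 6.55 against 2.99 ± 0.623 CPM (log2 fold change 3.17, SE 0.25, edgeR adjusted p = 2.07e-07), and Ly6c2 at 59.3 ± 12.7 against 9.71 ± 6.26 (log2 fold change 2.60, SE 0.34, edgeR adjusted p = 5.46e-05). Of the monocyte and macrophage markers 5 of 18 were higher, 1 lower and 12 not past the threshold (camera adjusted p = 0.00952, but adjusted p = 0.198 with an estimated correlation). In this list 7 were higher and 2 lower adjusted over the list alone. Csf1r was 58.3-fold higher (exact 95% counting interval 19.5 to 286), on 3 fragments in Tfh. Cd68, a lysosomal protein, was lower at 7.89 ± 2.27 against 20.2 ± 4.45 CPM. Of the erythroid and platelet markers 1 of 8 was higher, 0 lower and 7 not past the threshold (camera adjusted p = 0.660). The counts were 1 higher and 0 lower adjusted over the list alone. Hbb-b1 had 89 of its 173 fragments in memory-like replicate 3. Against a fold of 1.5, 173 genes were higher and 155 lower in memory-like than in Tfh cells, and limma on unfiltered log2(FPKM + 1) called 359 higher.

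The third comparison set memory-like cells against Th1 cells, and genes of cytotoxic and memory function differed in opposite directions. Ccl5, a chemokine of effector cells (chromosome 11, 83525778 to 83530518), stood at 636 ± 43.2 CPM in memory-like against 5022 ± 255 in Th1 cells (log2 fold change -2.98, SE 0.17, edgeR adjusted p = 4.61e-09). Nkg7 stood at 391 ± 46.2 against 2312 ± 105 CPM (log2 fold change -2.56, SE 0.16, edgeR adjusted p = 1.68e-08). Gzmb, granzyme B (chromosome 14, 56258838 to 56262260), stood at 21.1 ± 8.04 against 128 ± 15.1 CPM (log2 fold change -2.65, SE 0.23, edgeR adjusted p = 8.07e-07). Ccr7, the receptor for homing to lymphoid tissue (chromosome 11, 99144196 to 99155077), was higher in memory-like cells at 343 ± 39.9 against 35.5 ± 11.3 CPM (log2 fold change 3.28, SE 0.21, edgeR adjusted p = 1.81e-08). So were Tcf7 at 698 ± 67.2 against 182 ± 29.9 CPM (log2 fold change 1.94, SE 0.11, edgeR adjusted p = 4.61e-09) and Id3 at 208 ± 8.75 against 25.7 ± 3.04 (log2 fold change 3.01, SE 0.11, edgeR adjusted p = 1.93e-11). Neither is particular to memory-like cells: Tcf7 stood higher still in Tfh, and both were lower in Th1 than in Tfh cells. In all, 568 genes were higher and 679 lower in memory-like cells, of which 209 and 258 differed by at least 2-fold. Both counts moved with single libraries: without Th1 replicate 3 they were 371 and 414, without memory-like replicate 1 353 and 392, and without memory-like replicate 2 427 were lower. Libraries of the pair did not overlap for 27.8% of genes, where chance gives 10%.

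Of the memory genes 14 of 30 were higher, 0 lower and 16 not past the threshold (camera adjusted p = 3.08e-28, and adjusted p = 0.00193 with an estimated correlation). It was 18 higher and 1 lower adjusted over the list alone. Slamf6, a receptor of stem-like T cells, stood at 1200 ± 89.5 against 430 ± 41.6 CPM. Among cytotoxic effector molecules 1 of 23 was higher, 14 lower and 8 not past the threshold (camera adjusted p = 3.14e-20, and adjusted p = 0.00525 with an estimated correlation). In this list 1 was higher and 17 lower adjusted over the list alone. Fasl stood at 10.5 ± 3.85 against 50.2 ± 12.3 CPM and Ctsw, a cathepsin of cytotoxic cells, at 56.97 ± 8.02 against 168 ± 13.8. Of the Tfh program 19 of 27 were higher, 1 lower and 7 not past the threshold (camera adjusted p = 6.08e-51, and adjusted p = 0.00193 with an estimated correlation). The counts were 20 higher and 1 lower adjusted over the list alone. Sostdc1 had a log2 fold change of 3.62 (SE 0.11, edgeR adjusted p = 5.51e-13). In the Th1 program 1 of 30 was higher, 19 lower and 10 not past the threshold (camera adjusted p = 3.08e-28, and adjusted p = 0.00525 with an estimated correlation). It was 1 higher and 21 lower adjusted over the list alone. Ifngr1 stood at 60.4 ± 7.26 against 231 ± 31.6 CPM and Selplg at 541 ± 39.6 against 1146 ± 142. In the Treg and Tr1 list 1 of 22 was higher, 7 lower and 14 not past the threshold (camera adjusted p = 0.000585, and adjusted p = 0.0430 with an estimated correlation). In this list 1 was higher and 8 lower adjusted over the list alone. Maf, a factor that drives Il10, stood at 146 ± 5.16 against 289.9 ± 65.5 CPM and Prdm1 at 72.7 ± 4.26 against 137 ± 10.6.

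Among coinhibitory receptors and exhaustion genes 2 of 24 were higher, 10 lower and 12 not past the threshold (camera adjusted p = 0.000726, but adjusted p = 0.190 with an estimated correlation). The counts were 2 higher and 12 lower adjusted over the list alone. Entpd1, the ectoenzyme CD39, stood at 49.4 ± 13.3 against 155 ± 26.5 CPM, and Cd200, the other way, at 196 ± 28.4 against 72.5 ± 5.08. Among T cell fate transcription factors 9 of 36 were higher, 6 lower and 21 not past the threshold (camera adjusted p = 0.000294, but adjusted p = 0.0537 with an estimated correlation). It was 12 higher and 10 lower adjusted over the list alone. Ascl2 stood at 17 ± 1.92 against 2.80 ± 0.641 CPM and Tox2 at 224 ± 6.01 against 114 ± 12.2. Among cytosolic ribosomal protein genes 27 of 54 were higher, 0 lower and 27 not past the threshold (camera adjusted p = 1.99e-15, but adjusted p = 0.255 with an estimated correlation). In this list 40 were higher and 0 lower adjusted over the list alone. Rplp0 stood at 4475 ± 223 against 3189 ± 50.96 CPM. Among proliferation genes 0 of 40 were higher, 11 lower and 29 not past the threshold (camera adjusted p = 2.45e-06, but adjusted p = 0.294 with an estimated correlation). The counts were 0 higher and 17 lower adjusted over the list alone. Mki67 stood at 56.1 ± 7.08 against 107 ± 24.4 CPM. Among monocyte and macrophage markers 0 of 18 were higher, 0 lower and 18 not past the threshold (camera adjusted p = 0.544). It was 0 higher and 0 lower adjusted over the list alone. Of the erythroid and platelet markers 0 of 8 were higher, 2 lower and 6 not past the threshold (camera adjusted p = 0.148). In this list 1 was higher and 4 lower adjusted over the list alone. Of the plasma cell markers 0 of 4 were higher, 1 lower and 3 not past the threshold (camera adjusted p = 0.0934). The counts were 0 higher and 2 lower adjusted over the list alone. Without Th1 replicate 3 both of these lists were called (camera adjusted p = 0.0186 and 0.0471). Over the alternatives the adjusted p of the erythroid and platelet list ran from 0.0186 to 0.678. That of the plasma cell list ran from 0.0111, given by fry, to 0.242. Of the dendritic cell markers 0 of 8 were higher, 2 lower and 6 not past the threshold (camera adjusted p = 0.372). It was 1 higher and 3 lower adjusted over the list alone. The largest decreases included Adgrg1, an adhesion receptor of effector cells, at 1.48 ± 0.349 against 38.5 ± 6.11 CPM (log2 fold change -4.74, SE 0.38, edgeR adjusted p = 3.91e-07). Adam8 stood at 2.16 ± 1.87 CPM (log2 fold change -4.80, SE 0.59, edgeR adjusted p = 3.78e-05) and Ccr2 at 2.66 ± 1.39 (log2 fold change -3.45, SE 0.41, edgeR adjusted p = 3.02e-05). Cd83, an activation marker, was higher at 96.9 ± 12.3 against 11.6 ± 7.04 CPM (log2 fold change 3.06, SE 0.29, edgeR adjusted p = 1.55e-06). Against a fold of 1.5, 119 genes were higher and 124 lower in memory-like than in Th1 cells, and limma on unfiltered log2(FPKM + 1) called 365 and 374.

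Genes above both other subsets numbered 331 in Th1, 274 in Tfh and 8 in memory-like cells. Without the filter on low counts 522 were highest in Th1 and 32 in memory-like cells, and limma on unfiltered log2(FPKM + 1) gave 177 and 1. In memory-like cells DESeq2 called 23 and thinning of all libraries 16. With all 3 groups simulated as equal in 20 draws, the highest counts were 0, 0 and 1. That setting lacks the difference between Th1 and Tfh, so it is no measure for the memory-like count. Those of Th1 included Ccl3, a chemokine, at 401 ± 128 CPM against 40.9 ± 28.9 in Tfh and 39.9 ± 14.1 in memory-like cells. Lilr4b stood at 97.2 ± 11.4 against 1.74 ± 0.528 and 9.94 ± 4.07. Those of Tfh included Apoc4 at 27.7 ± 2.90 CPM against 0.121 ± 0.140 in Th1 and 0.298 ± 0.351 in memory-like cells. Cxxc5, a factor that restrains Wnt signalling, stood at 127 ± 21.8 against 7.13 ± 2.21 and 9.04 ± 2.36. The 8 genes of the memory-like cells were Ccr7, Il7r, Zbtb32, Irf4, Pik3ip1, Adk, Tnfrsf25 and 1700019D03Rik, the last of which falls outside the naming rule and was added after its values were seen. Zbtb32, a transcription factor (chromosome 7, 30589681 to 30598909), stood at 316 ± 43.8 CPM against 98.5 ± 8.02 in Tfh and 138 ± 32.8 in Th1 cells. Irf4, a factor induced by receptor signals, stood at 103 ± 6.59 against 52.5 ± 5.11 and 52.7 ± 6.61 CPM, and Tnfrsf25, a costimulatory receptor, at 177 ± 12.03 against 90.7 ± 5.33 and 108 ± 12.01. Single libraries moved these counts. That of Th1 was 199 without Th1 replicate 3 and 208, 204 and 208 without memory-like replicates 1, 2 and 3, and that of Tfh 170 without Tfh replicate 1 and 176 without memory-like replicate 3. That of memory-like cells was 5 and 4 without Tfh replicates 1 and 3, and 5, 4 and 4 without memory-like replicates 1, 2 and 3.

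Over the 2801 genes called between Th1 and Tfh, memory-like libraries lay at a mean position of 0.480 ± 0.036 (SD, n = 3) on the line from Tfh at 0 to Th1 at 1. The libraries stood at 0.458, 0.460 and 0.521. Genes higher in Th1 gave 0.482 and genes higher in Tfh 0.477, so the position was near the middle for both. Among the named genes the position was uneven. On the log2 scale Sostdc1, Id3 and Tcf7 in memory-like cells (759, 208 and 698 CPM) lay nearer to Tfh. Bhlhe40 and Itgb1 (1016 and 1657 CPM) lay at the level of Th1 (948 and 1565 CPM).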

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

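No test in this part was chosen after the result was seen. Flagged were data left out of the main measurement: the 27 genes listed under 25 spreadsheet-date names held 184028 fragments over the 9 libraries. Their share was 0.205% to 0.230% per library. The date form does not tell which gene of a family a value belongs to, so no gene was read from it. Single libraries were not tested against the rest of their group.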

How the results depend on the processing

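Thinning all libraries to the shallowest, the Lars2 covariate and leaving out Lars2 were chosen after seeing the data, and the other alternatives before the data were examined. No result reversed. Of 7969 values of named genes under the alternatives, 7655 kept their side of the threshold, 306 lost it and 8 gained it. Of those that kept it, 14 values of 7 results changed sign without being called in either fit. List calls kept their side in 942 values, were lost in 44 and gained in 28. Of those gained, 14 came from leaving out a library and nearly all others from fry, which asks another question than camera. Leaving out a library ended the calls of 6 list tests and made 9 others pass. The 6 were heat shock in Th1 against Tfh and in memory-like against Th1, cytokines and coinhibitory receptors in memory-like against Tfh, and cytokines and CD4 identity in memory-like against Th1. Among the scalings, list medians changed sign only for immediate early genes in memory-like against Tfh, from -0.0032 with TMM to 0.0030 with upper quartile scaling.

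A fold threshold of 1.5 left 588 genes higher and 421 lower in Th1 than Tfh, 173 and 155 in memory-like against Tfh, and 119 and 124 in memory-like against Th1, fewer by its own construction. With limma on log2(FPKM + 1) without a filter, 359 genes were higher in memory-like than Tfh, 365 higher and 374 lower than Th1, and 177 were highest in Th1 and 1 in memory-like. With log2(FPKM + 0.1), 205 were highest in Th1. Without the filter on low counts, 522 were highest in Th1 and 32 in memory-like. DESeq2 called 23 highest in memory-like, with all 8 of the main test among them, and thinning 16, also with all 8. The estimated correlation left 12 list calls. The cause was not tested for any of these but the fold threshold.

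Without each library in turn, genes higher in Th1 than Tfh numbered 1145 to 1473 and lower 954 to 1278. Memory-like against Tfh gave 418 to 573 higher and 361 to 531 lower, and against Th1 353 to 588 higher and 392 to 707 lower. The F test called 2168 to 2669. Highest in Th1 were 199 to 316, in Tfh 170 to 262 and in memory-like 4 to 11, list calls numbered 34 to 39, and the position was 0.437 to 0.521. No call turned its direction, and the lowest share kept was 708 of 1247, in memory-like against Th1 without memory-like replicate 1.

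With the replicate number as a block every count of genes rose. Highest in Th1 were 499 genes and in memory-like 17. The other counts stayed within 1.5 times, such as 933 genes lower in memory-like than Th1, against 679 without the block. Cd44 in memory-like against Th1, not called without the block, passed with it (log2 fold change -0.25, edgeR adjusted p = 0.0270). Lost in Th1 against Tfh were Il23r and Ppbp (edgeR adjusted p = 0.0570 and 0.0573). The chemokine list was lost in memory-like against Th1 (camera adjusted p = 0.0575). Oxidative phosphorylation was gained in Th1 against Tfh (camera adjusted p = 0.0450). Same-numbered libraries deviated together with correlations of 0.0138 to 0.0986, under the 0.1 asked of every pair for a paired design, and other pairs with -0.0625 to 0.0303. The highest correlation of all 9 libraries was with one of their own number, a hint of pairing from the data that the labels do not give.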

Other observations

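Of the tests below, those of depth, of a mixture of cells, of macrophage RNA and of the Lars2 covariate were chosen after the results were seen, and the splits of the libraries before. The search for ribosomal RNA was prompted by the Lars2 values and set before its own result was seen. Gcg, Pcsk1, Serpinc1 and Ntrk3, which belong to none of the lists, were among the largest changes between memory-like and Th1 cells. Gcg, the glucagon gene, stood at 34.4 ± 12.4 CPM in Th1 against 2.47 ± 2.75 in Tfh and 1.71 ± 2.44 in memory-like cells (log2 fold change -4.08, SE 0.72, edgeR adjusted p = 0.00120 for memory-like against Th1). Pcsk1, a protease that processes prohormones, stood at 19.7 ± 8.03 CPM in memory-like against 1.04 ± 1.01 in Th1 cells (log2 fold change 4.21, SE 0.61, edgeR adjusted p = 0.000195). Serpinc1, antithrombin, stood at 15.02 ± 3.69 against 0.767 ± 0.584 CPM (log2 fold change 4.24, SE 0.54, edgeR adjusted p = 5.78e-05), and Ntrk3, a neurotrophin receptor, at 35.8 ± 1.93 against 4.61 ± 2.22 (log2 fold change 2.96, SE 0.27, edgeR adjusted p = 1.48e-06).

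Genes below both other subsets in memory-like cells, a count made after seeing the data, numbered 5: Ccl5, Ier3, Ikzf3, Dgkd and Asb2. Ier3, an early response gene, stood at 8.33 ± 2.22 CPM against 28.1 ± 5.21 in Tfh and 30.8 ± 7.69 in Th1 cells.

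Few genes were highest in memory-like cells, whose libraries lay between the other subsets. With all libraries thinned to 3461936 fragments in 1 draw, 341 genes were highest in Th1, 280 in Tfh and 16 in memory-like cells. The Tfh count was still 17.5 times the memory-like one, which argues against depth as the whole cause. However, the memory-like count rose from 8 to 16, and the bound for the ratio was set after the data were seen. A plain blend of Tfh and Th1 cells, which the gate also removes, lies between its parts for every gene, but 8 genes were called above both, 23 by DESeq2 and at least 4 without any library, though 1 by limma on unfiltered log2(FPKM + 1). Ccr7 and Il7r were among them in the 16 edgeR and DESeq2 fits examined gene by gene. By the splits below chance is not excluded for that count. The 8 other splits that gave as many all kept Tfh or Th1 whole. Of the 88 that kept no real subset whole 0 did. Such splits mix the subsets within groups, which leaves few calls of any kind, so they decide nothing for the 8 genes. A blend with further cell types, and a distinct state of the sorted cells, may both give a middle position.

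Lars2 is a mitochondrial tRNA ligase outside the naming rule and was chosen after its values were seen. In replicates 1 to 3 it held 0.296%, 0.781% and 1.17% of fragments in Tfh and 0.629%, 1.66% and 3.32% in Th1. In memory-like libraries it held 0.361%, 0.487% and 0.500%. The share thus rose with the replicate number in each subset, and the fit below did not pair libraries by number. Lars2 stood at 19000 ± 13910 CPM in Th1 against 7432 ± 4346 in Tfh (log2 fold change 1.35, SE 0.44, edgeR adjusted p = 0.0313) and 4457 ± 703 in memory-like cells (log2 fold change -2.09, SE 0.45, edgeR adjusted p = 0.00536). With the Lars2 level within groups as a covariate at least 99.2% of each comparison's calls were kept, but such a covariate cannot change a difference between groups, so this decides nothing. Fragments of ribosomal RNA assigned to Lars2 may be a source of the spread. Its 9 transcripts were searched against 359 transcripts, those annotated as ribosomal RNA and any of the genes Gm42418 and AY036118. The longest match at 95% identity was 16 bases. The nuclear 45S precursor was not listed among them as such, so ribosomal fragments cannot be told apart from a change in Lars2 itself.

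Some macrophage transcripts were higher in Th1 and memory-like than in Tfh libraries, but the list was not called in Th1 (camera adjusted p = 0.197, though 0.0230 without Tfh replicate 2) and its call in memory-like cells was lost (adjusted p = 0.198 with an estimated correlation). Of the listed macrophage genes other than C1qa, C1qb and C1qc with a mean under 10 CPM, 80% (8 of 10) had a higher mean in both subsets than in Tfh, but the bound of 80% was set after the values were seen and expression by the sorted cells would give such a share too. Of the 5 members above 10 CPM 1 did, and Cd68 (20.2, 12.4 and 7.89 CPM in Tfh, Th1 and memory-like cells) went the other way. The most abundant of the C1q genes, C1qb, stood at 13 ± 4.72, 12.4 ± 3.91 and 3.24 ± 3.08 CPM in Th1, memory-like and Tfh cells. RNA of macrophages, cells that the gate would remove, and expression by the sorted cells cannot be told apart here, since no measure of this table separates them.

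Other splits of the libraries were run with the same tests. The 6 libraries of a pair allow 10 splits, too few for a share under 0.05. For gene counts the real split, 1 of the 10, gave 1498 higher and 1303 lower in Th1 than Tfh, 579 and 498 in memory-like than Tfh, and 568 and 679 in memory-like than Th1, and the highest of the others was 0 in each. For list calls the real values and the highest of the others were 11 and 13 in Th1 against Tfh, where 3 of 10 splits gave as many, 13 and 11 in memory-like against Tfh, and 13 and 8 in memory-like against Th1. Of 100 splits of the 9 libraries into 3 groups, 1 gave as many genes in the F test (2674, highest other 861), 1 as many as were highest in Th1 (331, highest other 143) and 1 as many as were highest in Tfh (274, highest other 143). In each case that was the real split. This argues against libraries that do not differ by subset at all. It does not test the Th1 and Tfh counts apart, because most other splits mix the subsets within groups, which leaves few calls of any kind. For the 8 genes highest in memory-like cells chance is not excluded by this count, since 9 of 100 gave as many (highest other 143). Each other split was counted by its largest group, whichever subset that held, so the count does not decide about memory-like genes. The other splits with 8 or more all kept Tfh or Th1 whole, so their large counts point to these subsets. Drawn splits that kept the memory-like subset whole gave 0 genes highest in any group, so they lend the 8 genes no support. With all 3 groups simulated as equal, at most 1 gene was highest in memory-like cells in 20 draws. That setting lacks the difference between Th1 and Tfh, so it does not decide whether the 8 genes arose by chance.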
